A study of Homo sapiens with 6 samples.

How the data were processed

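RNA was profiled in HEK293, an established human embryonic kidney cell line, as wild-type cells and as an NSUN2-deficient line that the labels say was made with CRISPR-Cas9. Each group holds 3 libraries, numbered as replicates 1 to 3 in the labels. The labels do not say whether replicates came from separate cultures, and they describe a single knockout line, so p-values measure only the spread between these libraries, which may be technical. Per the labels, RNA was extracted with TRIzol and the libraries were made with a kit that does not mark the strand of the RNA. The labels name both poly(A) RNA and a ribosomal RNA removal kit, and which of them set the composition of the libraries is not given in the sources used here.

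The deposited count of each gene in each library is a whole number of reads, raw per the file headers, and the columns sum to different totals. Per the submitters' processing notes, the tools were bcl2fastq 2.17.1.14, cutadapt, HISAT2 2.0.1, HTSeq 0.6.1 and DESeq2 1.6.3 with the genome build hg19, and the notes give no role or order for them. The annotation release and the strand setting of the counting are not given in the sources used here. The deposited RPKM values, named so per the file headers, stand beside the counts. In 2662 genes with RPKM above 10, the length implied by count and RPKM varied between the 6 libraries by a coefficient of variation within 1%, so a common length per gene lies behind them. That length was not the length column of the same table. The RPKM values entered no test. The authors' deposited table of changed genes gives a log2 fold change and a p-value per gene, per the file headers, and whether its p-value is adjusted is not stated there. The count columns were matched to samples by name and replicate number. The letters NK in the column names of 3 libraries were read as the knockout because the other 3 names match the wild-type line, and the level of NSUN2 reported with the results is a check of that reading, not its basis.

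The count table holds 57905 gene rows, of which 35989 have at least 1 count. The library totals were 36913891 to 40822527 counts in the wild type and 40497618 to 45100246 in the knockout. Differences between groups were tested with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr (minimum count 10, minimum total count 15), which left 18956 genes, libraries were scaled by TMM, and robust quasi-likelihood fits were tested by group with 2-sided F tests. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p below 0.05. CPM are counts scaled to a common library size after TMM, given as the mean ± SD over n = 3 libraries. Fold changes are knockout over wild type, with the standard error derived from the F statistic. Correlations and principal components used log2 CPM with a prior count of 2. Pairs of replicates were compared by chi-square over genes with at least 20 counts to look for a library deposited more than once, and none was found. All intervals implied by these errors cover the spread between libraries and not systematic differences in processing.

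Before the data were examined, 32 gene lists with 956 entries were written from general knowledge, of which 954 were found in the count table. They cover RNA methylation, translation, stress responses, the cell cycle, metabolism, interferon and other signalling, adhesion and matrix, HOX genes, RNAs without a poly(A) tail, and markers of other cell types. Lists with at least 5 tested members, 29 in all, were tested with camera (limma 3.58.1, 2-sided) at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Genes named in the text follow a rule also set beforehand: NSUN2, the 10 largest changes in each direction among called genes with a mean of at least 4 CPM and no overlap between the groups, the 2 most abundant called genes per direction with an absolute log2 fold change of at least 1, up to 2 higher and 2 lower members per list by adjusted p (the most abundant member where none was called), and the NSUN and TRDMT1 family. Other genes, named as called members of a list, as members that passed when adjusted over the list alone, at the ends of stretches of neighbouring genes or in the closing observations, were chosen after their values were seen. Some genes that the rule selects are not reported here, and no other gene took their place.

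Gene types, transcript length, GC content, chromosomes and the order of neighbouring genes came from GENCODE release 29, matched by gene ID for 90.4% of the rows. Transcript length and GC content were those of the longest annotated transcript of each gene. That release is on another genome build than the one the counts were made on, so no coordinates are given. Tested genes with a mean of at least 1 CPM were put in order along each chromosome and split into windows of 50, and window medians were set against 1000 random gene orders. Gene Ontology terms were taken from the deposited table, and terms with 10 to 300 tested genes were tested with a 1-sided Fisher's exact test. The tests were checked on simulated counts for this comparison (18664 genes in the step). Of 50 genes changed at each size, 0 were recovered at 1.5-fold, 21 at 2-fold, 37 at 4-fold and 47 at 8-fold, with 9 calls on unchanged genes. A simulated shifted list was called and 0 of 28 unchanged lists were. The simulated genes were drawn independently, with the same dispersion per gene in all libraries. The check therefore cannot show how the list test handles members that vary together, or how 1 outlying library affects the recovery of genes.

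The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a filter at a mean of 4 CPM, a fit without the robust option, a replicate block, a test against a 1.2-fold change (glmTreat), and each library left out in turn. After the data were seen, limma-voom with library weights and a fit with window medians removed were added. For these 2 fits, DESeq2, limma-voom and glmTreat, camera was run on z statistics per gene (cameraPR in limma) and not on the counts. Reads shared by overlapping genes or near-identical copies cannot be assigned with certainty. All 13 mitochondrially encoded mRNAs are listed at 0 in every library and were not analysed here.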

Results

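The study asked how loss of NSUN2, an enzyme that places 5-methylcytosine on tRNAs and other RNAs, changes the mRNA profile of HEK293 cells. Gene counts were compared between 3 wild-type libraries and 3 libraries of the NSUN2 knockout line. Depth was similar in the groups, at 36913891, 37237433 and 40822527 counts in wild-type replicates 1, 2 and 3 and 40497618, 42695749 and 45100246 counts in knockout replicates 1, 2 and 3.

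NSUN2 (ENSG00000037474) fell 16.2-fold in the knockout, from 196 ± 4.79 CPM to 12.1 ± 2.43 CPM (SD, n = 3). Its raw counts were 7685, 7380 and 8121 in the wild-type libraries and 438, 478 and 590 in the knockout libraries, so all 6 libraries matched their labels. The log2 fold change was -4.02 ± 0.17 (SE), with an edgeR adjusted p of 0.000194. An exact 2-sided permutation test of the CPM gave p = 0.10, the smallest value that 3 against 3 libraries allow. Among relatives of NSUN2, NSUN7 fell from 4.14 ± 0.14 to 0.82 ± 0.16 CPM (log2 fold change -2.33 ± 0.19, adjusted p = 0.00182). NOP2, NSUN3, NSUN4, NSUN5, NSUN6 and the tRNA methyltransferase TRDMT1 were not called, with log2 fold changes between -0.28 and 0.58 and adjusted p from 0.056 for NSUN6 to 0.773 for NSUN3. Without knockout replicate 3, NSUN6 (log2 fold change 0.46, adjusted p = 0.0152) and NSUN4 (-0.21, adjusted p = 0.0455) were called, and NSUN6 was also called without knockout replicate 2 (adjusted p = 0.0386), with DESeq2 (0.00931) and with library weights (0.00556).

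**Figure D1:**
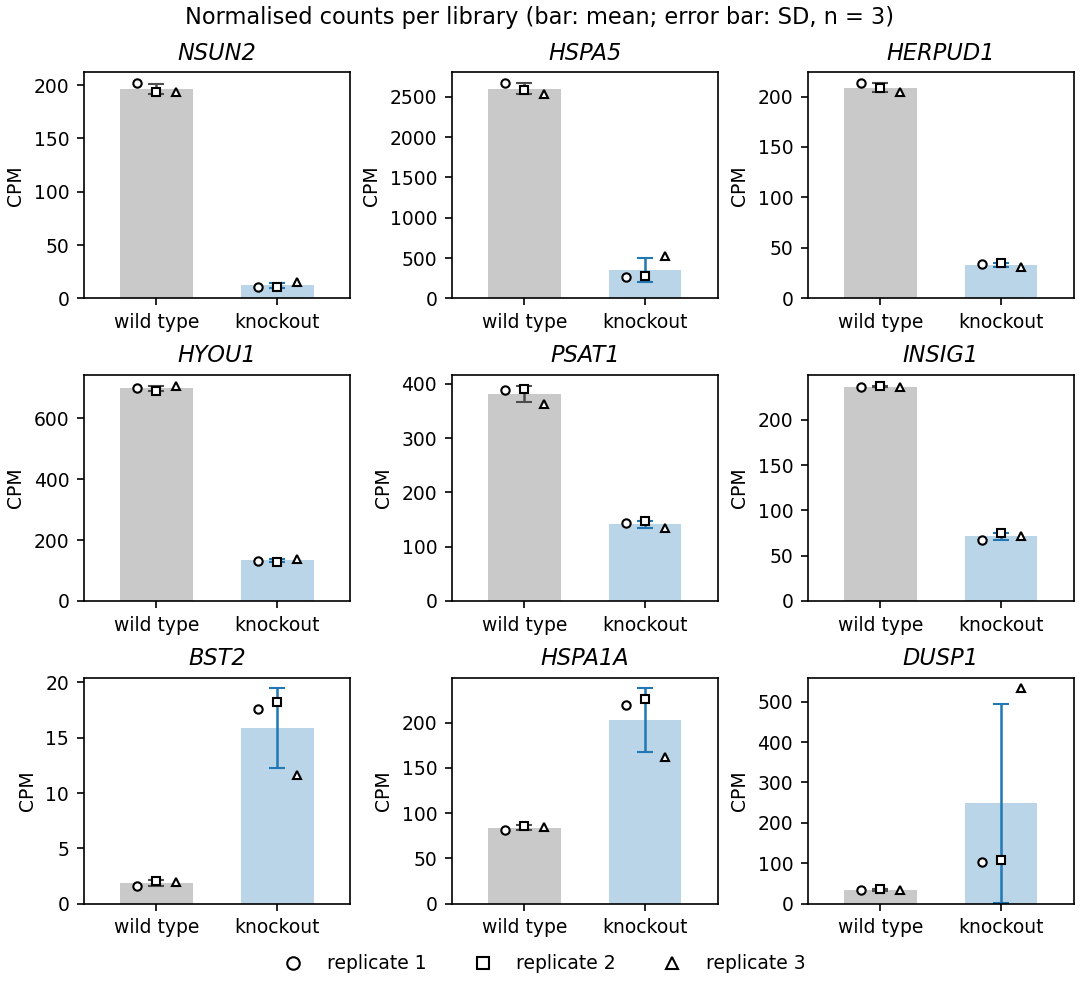
Normalised counts (CPM, linear axis from 0) of 9 genes in the wild type and the knockout; bars are means, error bars the SD over n = 3 libraries, and open symbols single libraries. NSUN2 lay at 10.6 to 14.9 CPM in the knockout libraries, HSPA5, HERPUD1, HYOU1, PSAT1 and INSIG1 were lower in every knockout library, BST2 and HSPA1A were higher, and DUSP1 reached 533 CPM in knockout replicate 3 against 103 and 109 CPM in the other knockout libraries.

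The wild-type libraries resembled each other closely, with Pearson correlations of log2 CPM across genes of 0.995 to 0.996. Knockout replicates 1 and 2 correlated at 0.990, whereas knockout replicate 3 correlated with them at 0.975 and 0.967 and with the wild type at 0.952 to 0.956. Knockout replicate 1 correlated with the wild type at 0.974 to 0.976 and knockout replicate 2 at 0.980. Genes are not independent replicates, and these values only describe the libraries. In knockout replicate 3, mRNAs of cytosolic ribosomal proteins took 12.0% of all counts, against 6.82% to 7.68% in the other 5 libraries, and the 100 most abundant genes took 20.5%, against 14.8% to 16.1%. All replicate pairs differed by more than sampling noise (chi-square per degree of freedom 3.42 to 6.31 in the wild type, 33.1 between knockout replicates 1 and 2, 159 and 208 for pairs with replicate 3).

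Of 18956 tested genes, 1880 were called, 908 higher and 972 lower in the knockout, and 822 of them had an absolute log2 fold change of at least 1 (437 higher, 385 lower). Most were protein-coding (788 higher and 814 lower). SYT1, a calcium sensor of synaptic vesicles, rose from 1.16 ± 0.09 to 17.7 ± 1.85 CPM (log2 fold change 3.93 ± 0.16, adjusted p = 0.000194). NELL2, a secreted neuronal glycoprotein, rose from 8.51 ± 0.52 to 84.3 ± 11.2 CPM, and the adhesion molecules CNTN1 and CHL1 rose by log2 fold changes of 3.66 ± 0.24 and 3.12 ± 0.22. PDE3A, a cyclic nucleotide phosphodiesterase, had the largest log2 fold change of the 10 named increases (4.43 ± 0.43), followed by HCLS1, a haematopoietic signalling adaptor (4.16 ± 0.19). TAF7, a subunit of the general transcription factor TFIID, rose from 14.8 ± 0.67 to 203 ± 37.7 CPM. The sulfate and carboxylate transporter SLC13A4 rose by 3.53 ± 0.17 and the antiviral tetherin BST2 by 3.08 ± 0.23 on the log2 scale. DUSP1, an immediate early phosphatase, was called at 2.87 ± 0.67 (adjusted p = 0.0454), and without knockout replicate 3 its log2 fold change was 1.62. HINT1 and COX7C were the most abundant large increases, at 491 ± 132 and 495 ± 211 CPM in the knockout, and the log2 fold change of COX7C, 1.23, was 0.81 without knockout replicate 3. All 1880 called genes had groups that did not overlap, as did 43.4% of all tested genes, where chance gives 10%. The count of called genes was 6610 without knockout replicate 3, 3140 without knockout replicate 2, 458 without knockout replicate 1, and 251, 216 and 211 without wild-type replicates 1, 2 and 3.

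Among the decreases, MYD88, the adaptor of Toll-like receptors, fell from 12.2 ± 0.45 to 0.65 ± 0.06 CPM (log2 fold change -4.22 ± 0.16, adjusted p = 0.000194). ESRP1, an epithelial splicing regulator, fell from 15.2 ± 0.23 to 0.93 ± 0.66 CPM. FRRS1L, a component of glutamate receptor complexes, fell by 4.84 on the log2 scale, the orphan receptor GPR50 by 4.59 and the G-protein regulator RGS3 by 3.67. SDR42E1 and CPXM1 had log2 fold changes of -3.50 ± 0.34 and -3.10 ± 0.30. HSPA5, the main chaperone of the endoplasmic reticulum, was the most abundant of these genes and fell from 2598 ± 67.9 to 355 ± 149 CPM (log2 fold change -2.87 ± 0.30, adjusted p = 0.00405). Fibronectin, FN1, fell from 1120 ± 68.0 to 360 ± 133 CPM. Exons of PDE3A, SYT1, TAF7, SLC13A4, CHL1, COX7C, GPR50 and SDR42E1 overlap another annotated gene, and without strand their counts are uncertain. The same holds for HYOU1, HSPA1B, IFITM1, IFITM3, IER3, HARS, UTP15, NDUFB3, CDKN2A, TYMS, CHAF1A, BBC3, KIF2C, ALDOC, VEGFA, SRXN1, SLC7A11, PMEPA1, COL9A3, COL3A1, LOXL2, CLDN7, NEFM, NEFH, NCAM1, NOP2, NSUN3, NSUN6, CARS, DUSP6, KIF20A, NUSAP1, WT1, POLD1, NQO1, SYP, AQP1, PCDHA10, PCDHB2 and PCDHB15. LHX1 and HIST1H2AH had no match in the annotation and were not checked for overlap. Of 86 genes named by the preset rule that were called, 50, 51 and 51 were not called without wild-type replicates 1, 2 and 3, 42 without knockout replicate 1, 2 without knockout replicate 2 and 1, CDK1, without knockout replicate 3, and 0 changed sign.

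**Figure D2:**
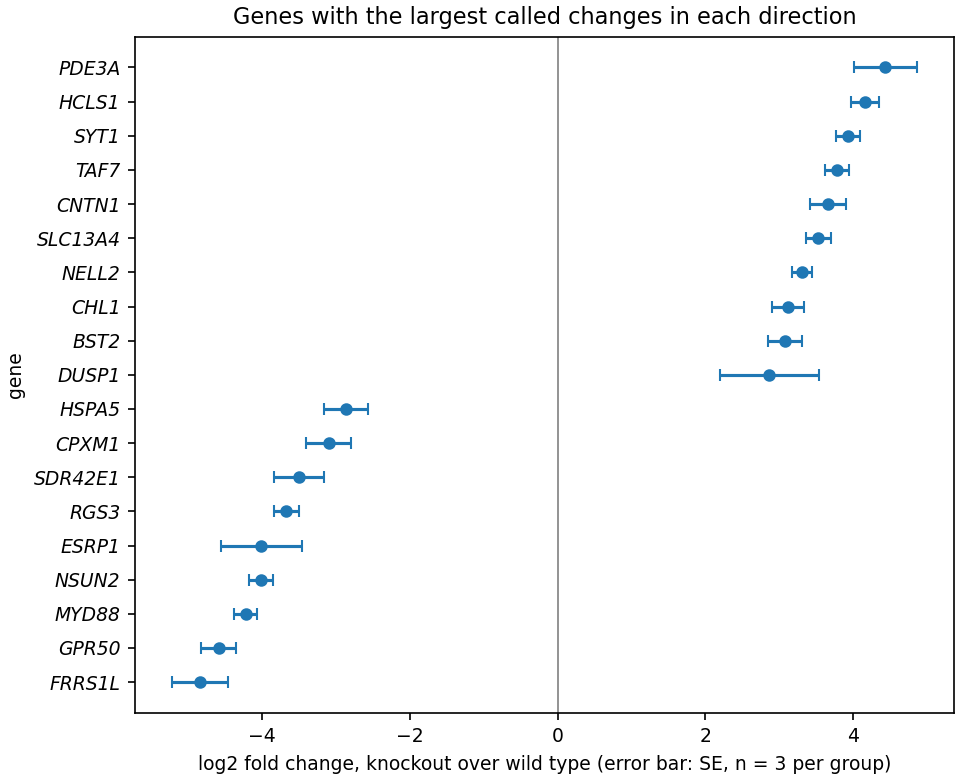
Log2 fold change of knockout over wild type (horizontal axis) of reported genes with the largest called changes in each direction (vertical axis). Only genes with a mean of at least 4 CPM and no overlap between the groups were ranked. Points are fitted values and error bars the SE, n = 3 libraries per group. The changes run from -4.84 for FRRS1L to 4.43 for PDE3A, and DUSP1 has the widest error bar, 0.67.

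Genes of the unfolded protein response, the XBP1 and ATF6 programme that supplies chaperones and degradation factors to the endoplasmic reticulum, were lower in the knockout. Of 22 tested members, 14 fell, 0 rose (0 at an unadjusted p under 0.05 in edgeR, 0 in DESeq2) and 8 were not called, with a median log2 fold change of -1.06; adjusted over the list alone, 19 fell. HERPUD1, a factor of protein disposal from the endoplasmic reticulum, fell from 209 ± 4.57 to 33.2 ± 1.85 CPM, and the chaperone HYOU1 from 699 ± 7.92 to 133 ± 4.78 CPM. The list median was -1.13, -1.17 and -0.95 in knockout replicates 1, 2 and 3 relative to the wild-type mean. Camera gave an adjusted p of 1.38e-22, and the adjusted p was 0.0656 with an estimated correlation. The count of lower members was 22 without knockout replicate 3, 9 without knockout replicate 1 and 8 without any 1 wild-type replicate.

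Targets of ATF4, the transcription factor of the integrated stress response, fell alongside. Of 26 tested members, 17 fell, 0 rose (1 at an unadjusted p under 0.05 in edgeR, 0 in DESeq2) and 9 were not called (median -0.67); adjusted over the list alone, 19 fell and 1, ATF3, rose. PSAT1, an enzyme of serine synthesis, fell from 381 ± 15.3 to 142 ± 6.45 CPM, and CHAC1, which degrades glutathione, from 27.8 ± 1.35 to 8.95 ± 0.52 CPM. With camera the adjusted p was 4.65e-18, and the adjusted p was 0.0161 with an estimated correlation. The count of lower members was 23 without knockout replicate 3, 11 without knockout replicate 1, 9 without wild-type replicate 2 and 8 without wild-type replicate 1 or 3. Among the 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, AARS (-0.85 ± 0.09), IARS (-0.86 ± 0.10), CARS (-0.77) and NARS (-0.41) fell and HARS (0.72 ± 0.15) and RARS (0.70 ± 0.13) rose in log2 fold change. That list was not called (median -0.02, adjusted p = 0.41), and 5 fell and 4 rose when adjusted over the list alone. It was called lower without knockout replicate 3 (adjusted p = 0.0141).

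Enzymes of cholesterol biosynthesis and genes of cholesterol uptake fell in a similar proportion. Of 25 tested members, 15 fell, 0 rose (0 at an unadjusted p under 0.05 in edgeR, 0 in DESeq2) and 10 were not called (median -0.75); adjusted over the list alone, 20 fell. INSIG1, the sterol-regulated anchor of SREBP processing, fell from 237 ± 0.85 to 71.4 ± 3.85 CPM (log2 fold change -1.73 ± 0.09, adjusted p = 0.000421). Squalene epoxidase, SQLE, fell from 126 ± 3.67 to 49.5 ± 1.23 CPM. The list median was -0.76, -0.87 and -0.83 in the knockout libraries. The camera test had an adjusted p of 1.58e-17, and the adjusted p was 0.0311 with an estimated correlation. The count of lower members was 20 without knockout replicate 3, 10 without knockout replicate 1, and 8, 7 and 6 without wild-type replicates 1, 2 and 3.

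Interferon-stimulated genes moved mostly upward. Of 34 members, 12 rose, 2 fell and 20 were not called (median 0.46); adjusted over the list alone, 19 rose and 2 fell. BST2 rose from 1.88 ± 0.24 to 15.8 ± 3.62 CPM and IFITM1 from 1.80 ± 0.19 to 6.03 ± 0.16 CPM. The restriction factor IFITM3 fell from 7.86 ± 0.655 to 2.58 ± 1.07 CPM and the transcription factor IRF7 from 19.0 ± 0.47 to 11.1 ± 1.71 CPM. Camera gave an adjusted p of 4.00e-06, and the adjusted p was 0.0457 with an estimated correlation. The count of higher members was 17 without knockout replicate 3, 4 without knockout replicate 1 or wild-type replicate 1, and 2 without wild-type replicate 2 or 3. IFITM1 and IFITM3 belong to a family of similar genes, so reads could be divided between them.

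In the heat shock response, 7 of 19 members rose, 1 fell and 11 were not called (median 0.41); adjusted over the list alone, 10 rose and 1 fell. The inducible HSP70 genes HSPA1A and HSPA1B rose from 84.1 ± 2.51 to 203 ± 35.3 CPM and from 180 ± 5.06 to 348 ± 12.2 CPM, and since they are near-identical copies, the division of reads between them is uncertain. SERPINH1, a collagen chaperone, fell from 276 ± 5.42 to 194 ± 17.8 CPM. By camera the list had an adjusted p of 2.49e-06, and the adjusted p was 0.295 with an estimated correlation. The count of higher members was 12 without knockout replicate 3, 2 without wild-type replicate 2 and 1 without wild-type replicate 1 or 3.

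**Figure D3:**
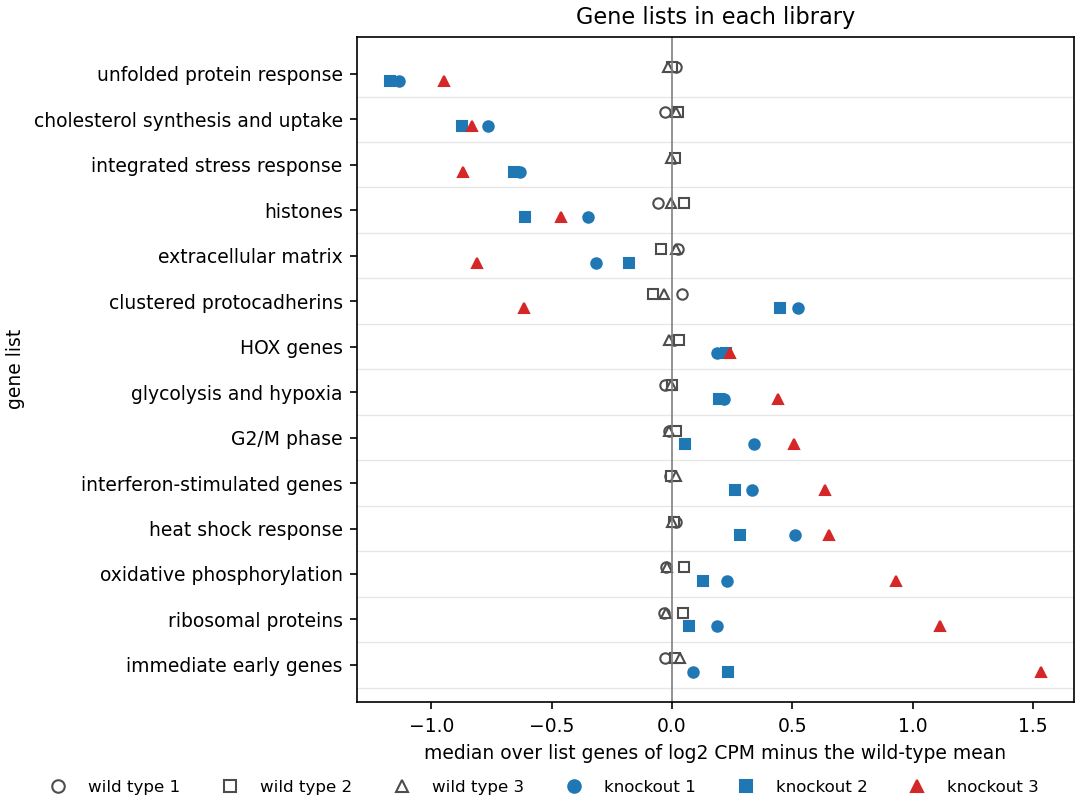
Median over the genes of each of 14 lists (vertical axis) of log2 CPM minus the wild-type mean (horizontal axis), with open symbols for wild-type libraries, blue for knockout replicates 1 and 2 and red for knockout replicate 3. The unfolded protein response lies between -1.17 and -0.95 in the 3 knockout libraries, whereas ribosomal proteins lie at 0.19 and 0.07 in knockout replicates 1 and 2 and at 1.12 in replicate 3.

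Several lists moved mainly with knockout replicate 3. Cytosolic ribosomal proteins had a median log2 fold change of 0.56, made of 0.19, 0.07 and 1.12 in knockout replicates 1, 2 and 3, and 1 of 78 members rose. Nuclear-encoded subunits of oxidative phosphorylation had library medians of 0.23, 0.13 and 0.93, and 6 of 74 members rose, among them COX7C and NDUFB3 (45.4 ± 2.45 to 82.3 ± 23.3 CPM). With p adjusted over the list alone, 0 members of either list passed in edgeR, with 11 and 32 higher at an unadjusted p under 0.05, and DESeq2 called 7 and 21 over all genes. Immediate early genes, which respond within minutes to stimulation, had library medians of 0.09, 0.23 and 1.53, and 3 of 23 rose: DUSP1, IER3 (25.8 ± 2.48 to 38.0 ± 3.40 CPM) and DUSP6 (log2 fold change 0.50). Ribosome biogenesis factors had library medians of 0.04, 0.03 and 0.48, and only UTP15 of 40 members rose (0.61 ± 0.11). Camera called these 4 lists higher (adjusted p = 6.64e-06, 1.44e-06, 0.0122 and 0.0221), and the adjusted p was 0.76, 0.76, 0.737 and 0.76 with an estimated correlation. Without knockout replicate 3, immediate early genes (adjusted p = 0.0699) and ribosome biogenesis factors (0.222) were not called, nor were they with library weights (0.255 and 0.122), and 26 ribosomal protein genes were higher and 9 lower, with a list median of 0.12. The same 3 immediate early genes and UTP15 rose when adjusted over the list alone. Without knockout replicate 2, 7 ribosomal protein genes, 22 oxidative phosphorylation genes and 9 ribosome biogenesis factors were higher. Without knockout replicate 3, 33 oxidative phosphorylation genes were higher and 7 lower, 9 immediate early genes higher and 4 lower, and 11 ribosome biogenesis factors higher and 4 lower. The calls of members of these 4 lists were lost without any 1 wild-type replicate or without knockout replicate 1. Clustered protocadherins, adhesion proteins of neurons, had library medians of 0.52, 0.45 and -0.62. PCDHA10 (0.83 ± 0.06 to 4.71 ± 1.12 CPM), PCDHB2 (7.43 ± 0.34 to 19.0 ± 2.53 CPM) and PCDHB15 (log2 fold change 2.15) rose among 24 members, as did PCDHB13 when adjusted over the list alone. That list was not called (adjusted p = 0.159), but was without knockout replicate 3 (adjusted p = 0.00177), where 9 members were higher, and with library weights (adjusted p = 0.0129). PCDHA10 and PCDHB2 lie on chromosome 5 in the window from EGR1 to ARAP3, with medians of 0.40, 0.37 and 0.43 in knockout replicates 1, 2 and 3. Of the 24 members, 14 lay in no window, so the removal of window medians did not correct them for such a shift.

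Extracellular matrix genes fell more often than they rose, also most in knockout replicate 3 (library medians -0.32, -0.18 and -0.81). Of 42 members, 10 fell, 4 rose and 28 were not called (median -0.45). COL5A1 fell from 87.0 ± 2.92 to 19.6 ± 7.99 CPM and the lysyl oxidase LOXL2 from 23.4 ± 1.47 to 8.45 ± 0.85 CPM. COL3A1 (3.22 ± 0.21 to 7.02 ± 1.15 CPM), COL9A3 (3.69 ± 0.23 to 6.98 ± 0.32 CPM), LUM and POSTN rose. With adjustment over all genes replaced by p adjusted over the list alone, 15 fell and 4 rose. The count of lower members was 20 without knockout replicate 3 (9 were then higher), 15 without knockout replicate 2 and 1 without knockout replicate 1 or any 1 wild-type replicate. With camera the list had an adjusted p of 0.000213, and the adjusted p was 0.737 with an estimated correlation. Replication-dependent histone genes fell in 8 of 35 members (median -0.61), including HIST1H2BJ (6.56 ± 0.52 to 2.71 ± 0.16 CPM) and HIST1H2AC (9.16 ± 0.56 to 4.11 ± 0.35 CPM), while HIST1H2AH rose at a level under 1 CPM. Most histone mRNAs of this class lack a poly(A) tail, and histone genes are close copies whose reads could be divided between them. In this list 12 fell and 2 (HIST1H2AH and HIST2H2AC) rose when adjusted over the list alone. The count of lower members was 11 without knockout replicate 3, 5 without knockout replicate 2, 2 without knockout replicate 1, and 2, 1 and 2 without wild-type replicates 1, 2 and 3. By camera the adjusted p was 0.000133, and the adjusted p was 0.295 with an estimated correlation.

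Of 34 G2/M phase genes, CDK1 (83.5 ± 6.70 to 196 ± 65.2 CPM), CCNB1 (266 ± 6.27 to 438 ± 64.6 CPM), KIF2C, KIF20A and NUSAP1 rose and UBE2C fell (median 0.32). The list median was 0.34, 0.06 and 0.51 in knockout replicates 1, 2 and 3, and CDK1 was not called without knockout replicate 3, at a log2 fold change of 1.02 ± 0.28 (adjusted p = 0.0641) against 1.23 with it. In the glycolysis and hypoxia list, 6 of 32 members rose and 1 fell (median 0.29), with ALDOC, an aldolase, at 2.44 ± 0.33 and 4.97 ± 0.15 CPM, the prolyl hydroxylase EGLN3 at 17.2 ± 0.77 and 25.5 ± 0.275 CPM, and VEGFA at 109 ± 2.40 and 79.2 ± 4.61 CPM in wild type and knockout. HOX genes, the homeobox regulators of body patterning, rose in 6 of 37 members (median 0.30), among them HOXB13 (log2 fold change 0.75). Camera called these 3 lists higher (adjusted p = 0.000418, 0.00241 and 0.00937), and the adjusted p was 0.668, 0.436 and 0.436 with an estimated correlation. The HOX list was not called without knockout replicate 2 (adjusted p = 0.127). Higher members numbered 12, 18 and 14 in these lists without knockout replicate 3, and 15, 5 and 5 without knockout replicate 2. Without knockout replicate 1 only 3 HOX genes were called among them, and the calls in all 3 lists were lost without any 1 wild-type replicate. Adjusted over the list alone, 6 G2/M phase genes, 8 glycolysis and hypoxia genes and 7 HOX genes rose, and 1, 1 and 0 fell.

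The remaining lists were not called. Among 14 other writers, readers and erasers of 5-methylcytosine, only NSUN7 fell (adjusted p of the list = 0.735), and the median of 0.13 and the mean of -0.08 differed in sign; NSUN6 rose and NSUN7 fell when adjusted over the list alone. Of 38 other tRNA modification enzymes, TRMT10C (1.52 ± 0.37) and GTPBP3 (0.76 ± 0.13) rose in log2 fold change and IKBKAP (-0.50 ± 0.10) fell (adjusted p = 0.397). Of 7 mRNAs reported as NSUN2 targets, CDK1 rose and the cell cycle inhibitor CDKN2A fell from 358 ± 27.9 to 150 ± 45.6 CPM (adjusted p = 0.693). CDKN2A lies on chromosome 9 and was not called with window medians removed (log2 fold change -0.89 against -1.25 before, edgeR adjusted p = 0.0621). Among 24 p53 targets, BTG2 (0.89 ± 0.17) and GADD45A (0.49 ± 0.10) rose and BBC3 (-0.81 ± 0.16) and SESN2 (-0.48 ± 0.11) fell (adjusted p = 0.41). Among 33 G1/S and S phase genes, 2 rose, among them CHAF1A, and TYMS fell (adjusted p = 0.534). TNFAIP2 alone rose among 17 NF-kB targets (adjusted p = 0.693; median 0.07, mean -0.07). Among 22 NRF2 targets, AKR1C1, AKR1C2 and ABCC2 rose and SRXN1 and SLC7A11 fell (adjusted p = 0.41), and AKR1C1 and AKR1C2 are close paralogs. ID3, an inhibitor of basic helix-loop-helix factors, rose from 67.3 ± 4.16 to 211 ± 51.7 CPM and SMAD6 by 0.81 ± 0.11 among 20 Wnt and TGF-beta targets, where PMEPA1 fell (adjusted p = 0.311). Of 31 integrin, cadherin and epithelial-mesenchymal genes, ESRP1, CLDN7 and ITGA3 fell (adjusted p = 0.0781). The p53 and the Wnt and TGF-beta lists were called higher without knockout replicate 3 (adjusted p = 0.0122 and 0.0117), and the integrin list was called lower without knockout replicate 1 (adjusted p = 0.0157), with no filter (0.00721), at a mean of 4 CPM or more (0.0357) and with window medians removed (0.0267). With library weights the p53 list was called higher (adjusted p = 0.0496). When p was adjusted over the list alone, 1 rose and 1 fell among the tRNA modification enzymes and among the reported targets, 3 and 3 among p53 targets, 2 and 2 among G1/S and S phase genes, 4 and 2 among NRF2 targets, 3 and 1 among Wnt and TGF-beta targets, 0 and 4 in the integrin list, and 0 and 0 among NF-kB targets in edgeR (3 and 5 at an unadjusted p under 0.05; 1 and 2 called by DESeq2 over all genes). Among the members gained were PLK2, POLD1, NQO1, ID1 and CDH4.

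Markers of other cell types gave no common direction. Of 20 neuron-like markers, NEFM rose (58.2 ± 1.18 to 120 ± 12.0 CPM) and NEFH (11.7 ± 0.38 to 2.10 ± 0.82 CPM), MAP2, NCAM1 and RTN1 fell (adjusted p = 0.962; median 0.10, mean -0.04). Of 18 kidney tubule and progenitor markers, LRP2 (37.8 ± 3.30 to 18.7 ± 2.66 CPM), LHX1 (27.5 ± 1.04 to 16.3 ± 1.92 CPM), and WT1 were among 4 that fell (adjusted p = 0.41; median 0.02, mean -0.14). Of 13 fibroblast and muscle-like markers, COL3A1 and LUM rose and MYL9 fell (adjusted p = 0.397). Adrenal steroidogenic markers and blood and immune cell markers had 4 tested members each, too few for the list test, and 0 were called in edgeR (1 and 2 at an unadjusted p under 0.05) or in DESeq2 (1 and 1); FDX1 lay at 58.0 ± 2.46 and 39.2 ± 13.9 CPM and CD14 at 1.33 ± 0.17 and 2.56 ± 1.34 CPM. FDX1 had a log2 fold change of -0.56, and it was called lower without knockout replicate 3 (-0.91, adjusted p = 0.000184) and with library weights (-0.90, adjusted p = 0.000119). FDX1 lies on chromosome 11, and with window medians removed its log2 fold change was -0.18 (edgeR adjusted p = 0.653). Its fall is therefore not separated from that of its neighbours. Among 9 abundant RNAs without a poly(A) tail, RNU5A-1 alone rose, at a level under 1 CPM (adjusted p of the list = 0.198). By p adjusted over the list alone, 2 rose (SYP besides NEFM) and 4 fell among neuron-like markers, 1 (AQP1) and 4 among kidney markers, and 2 and 1 among fibroblast and muscle-like markers. Among RNAs without a poly(A) tail 2 rose (SNORD3A besides RNU5A-1).

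Fold changes also followed the position of genes. On chromosome 9 the median log2 fold change was -0.39, with 161 of 756 tested genes lower and 9 higher, and on chromosome 11 it was -0.34, with 196 of 970 lower and 12 higher. On chromosome 5 it was 0.36, with 144 of 876 genes higher and 16 lower. The medians in knockout replicates 1, 2 and 3 were -0.38, -0.38 and -0.44 for chromosome 9, -0.36, -0.37 and -0.36 for chromosome 11, and 0.39, 0.29 and 0.29 for chromosome 5. Camera, run over chromosomes after these values were seen, gave adjusted p of 5.60e-17, 4.92e-14 and 1.75e-09 for chromosomes 9, 11 and 5, and the adjusted p was 0.00303, 0.000346 and 0.027 with an estimated correlation. The same test also called chromosome 6 higher (median 0.17, adjusted p = 0.0029, and adjusted p = 0.0537 with an estimated correlation) and chromosomes 16, 18 and 20 lower (medians -0.11, -0.19 and -0.17). For these 3 the adjusted p was 0.0106, 0.000628 and 0.000209, and it was 0.139, 0.0515 and 0.026 with an estimated correlation. Chromosome 14 was called only with an estimated correlation (median 0.14, adjusted p = 0.0473, against 0.175). Of 301 windows of 50 neighbouring genes, 17 lay below and 2 above the range of 1000 random gene orders, -0.38 to 0.53, and the longest stretches below it ran from DCAF10 to LAMC3 on chromosome 9 and from RAB39A to B3GAT1 on chromosome 11. Of the 17 windows, 8 lay on chromosome 11, 7 on chromosome 9 and 2 on chromosome 19, and both higher windows lay on chromosome 5. Smaller shifts followed position as well. On chromosome 19, windows from PPAP2C to RHPN2 had medians of 0.25 to 0.47, and those after RHPN2 ran from -0.49 to 0.28. On chromosome 14, windows from RP11-507K2.3 to TMEM121 lay at 0.36 to 0.40, and the earlier ones at -0.11 to 0.21. Of the named genes in such stretches, BBC3, CHAF1A, GTPBP3 and TNFAIP2 lost their calls with window medians removed, and BST2 kept it. Among the called genes named by the preset rule, FRRS1L, RGS3, HSPA5, COL5A1, PSAT1, CDKN2A, IARS and IKBKAP lie on chromosome 9 and were lower. HYOU1, IFITM3, IRF7, SERPINH1 and NCAM1, all lower, and IFITM1, higher, lie on chromosome 11. TAF7, DUSP1, PCDHA10, PCDHB2, COX7C, HINT1, HARS, CCNB1, RARS and UTP15, all higher, and NSUN2 itself lie on chromosome 5. The shift of chromosome 5 did not cover its start. Windows from PLEKHG4B to CCT5 and from CMBL to NUP155 had medians of 0.05 and -0.02, and those from WDR70 onward 0.27 to 0.59. The log2 fold change of NSUN2 was -4.06 with window medians removed, against -4.02 before. With the median of each window removed, 1017 genes were called, 890 of them among the 1880, and 28 of the 86 named genes were not called. Among those 28 were IKBKAP (-0.11), NCAM1 (-0.08), CCNB1 (0.14), SERPINH1 (-0.23), HARS (0.31), RARS (0.33), UTP15 (0.34), IARS (-0.39), IRF7 (-0.43), HINT1 (0.62) and COX7C (0.64), with the log2 fold change in that fit in parentheses, and DUSP1 (2.496 against 2.87 before, adjusted p = 0.0818). Other genes lost the call but kept most of their change. NDUFB3 lay at 0.90 against 0.86 before, HIST1H2AH at 1.74 in both fits, IFITM3 at -1.26 against -1.60 and LUM at 1.24 against 1.55. CDKN2A lay at -0.89 against -1.25. The calls of members of the ribosomal protein, oxidative phosphorylation, immediate early, ribosome biogenesis, tRNA modification and G1/S lists were lost, as were the higher calls among aminoacyl-tRNA synthetases, of which 2 were lower. TRMT10C, GTPBP3, CHAF1A and TYMS lay at 1.34, 0.43, 0.19 and -0.31 in that fit, against 1.52, 0.76, 0.58 and -0.48 before. The medians of the ribosomal protein, oxidative phosphorylation, immediate early and ribosome biogenesis lists were 0.49, 0.47, 0.81 and 0.23 in that fit, against 0.56, 0.47, 0.87 and 0.21 before. Camera at the preset correlation still called these 4 lists (adjusted p = 4.77e-09, 1.13e-08, 0.00331 and 0.00717). An estimated correlation was not run with window medians removed, and before the removal it gave camera adjusted p of 0.76, 0.76, 0.737 and 0.76. In that fit 2 glycolysis and hypoxia genes and 2 G2/M phase genes were higher and 5 histone genes lower, and 16 members of the unfolded protein response list, 16 of the integrated stress response list and 16 of the cholesterol list were lower. With it removed, 7 interferon-stimulated genes and 6 heat shock genes were higher, and the HOX list was not called (adjusted p = 0.0744).

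**Figure D4:**
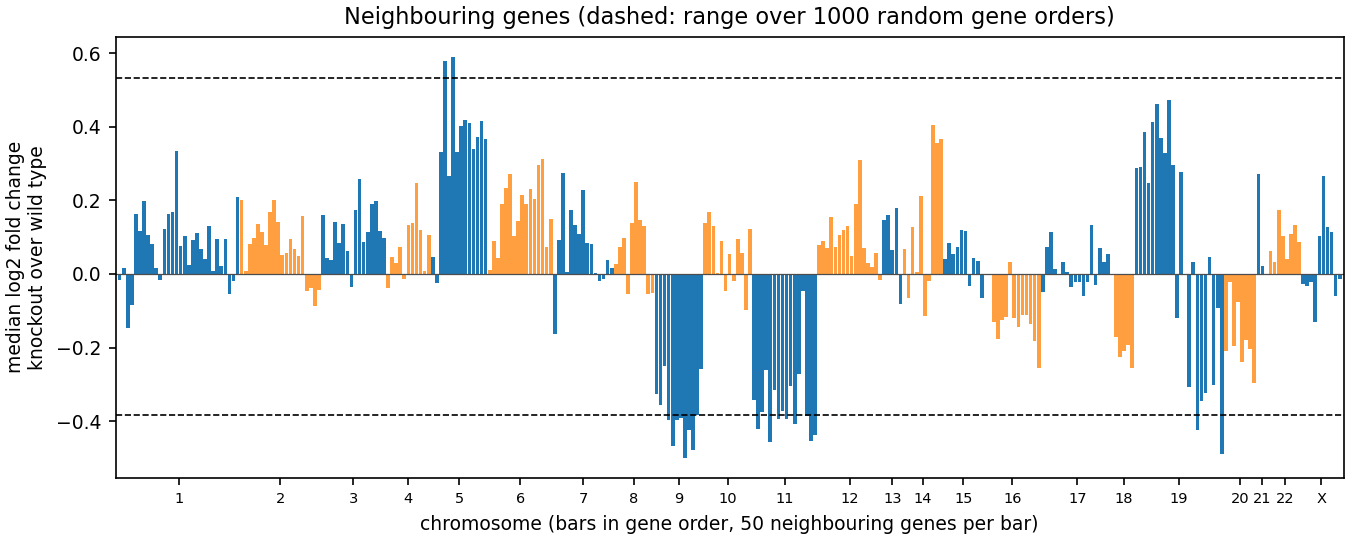
Median log2 fold change of knockout over wild type (vertical axis) in windows of 50 neighbouring tested genes, in gene order along the chromosomes (horizontal axis, colours alternate between chromosomes); dashed lines give the range over 1000 random gene orders, -0.38 to 0.53. All bars of chromosomes 9 and 11 lie below 0 and most bars of chromosome 5 above 0, with extremes over all chromosomes of -0.50 and 0.59.

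The authors' deposited table, as used here, lists 790 changed genes, 466 higher and 324 lower in the knockout, with absolute log2 fold changes from 1.00. Of these, 693 were tested in the refit, 692 had the same sign and 573 were also called with that sign. The refit fold changes correlated with those of the authors' deposited table at r = 0.968 across these genes, which are not independent replicates. Both come from the same series, which holds only these 6 libraries, so they are not separate experiments. A table of large changes only also makes a high correlation and the same sign likely. Of 822 genes called in the refit with an absolute log2 fold change of at least 1, 250 are not in it, 112 of them protein-coding. NSUN2 has a log2 fold change of -3.86 in the authors' deposited table. The authors' deposited table lists 9 of the 10 largest named increases and 7 of the 9 largest named decreases, and DUSP1, ESRP1 and HSPA5 are not among its genes. The overlap of 573 genes was 179 to 299 without a wild-type replicate or knockout replicate 1.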

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

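Limma-voom with library weights and the removal of window medians were chosen after seeing the data. The log2 fold change of NSUN2 in knockout versus wild type ran from -4.21 to -3.93 and was called under every alternative run. The number of genes changed in knockout versus wild type, with the genes higher in knockout and the genes lower in knockout, was 3797 (1966, 1831) with DESeq2 and 6616 (3408, 3208) with library weights, where knockout replicate 3 had a weight of 0.0743; the cause of the DESeq2 count was not tested. At a mean of 4 CPM or more, which tested 12620 genes, 1242 were called, 507 of them higher. The count of genes changed by an absolute log2 fold change of 1 or more was then 274, and the overlap with the authors' deposited table of changed genes 213. A test against a 1.2-fold change called 804 (374, 430), and the removal of window medians gave 1017 (454, 563), of which 890 were among the 1880. Replicate numbers showed no pairing of the libraries: same-numbered deviations correlated at -0.016, -0.14 and 0.003, and no library correlated best with its own number. Deviations were taken from means of 3 libraries, and knockout replicate 3 lay far from the others, so a small shared effect could be missed. A replicate block, which leaves fewer residual degrees of freedom, called 374 (175, 199), with 346 changes of that size and an overlap of 296. With a library left out, the calls ran from 211 to 6610 (85 to 3269 higher, 126 to 3341 lower), the changes of that size from 204 to 1456 and the overlap from 179 to 689. Fewer samples entered these fits, and other causes were not tested. Without knockout replicate 3, 1875 of the 1880 genes remained called with the same sign. Of the 29 tested lists 14 were called, 3 with an estimated correlation and 8 with fry. The estimated correlation, which allows for members that vary together, ended the calls of the unfolded protein response (median -1.06, adjusted p = 0.0656) and heat shock (median 0.41, adjusted p = 0.295) lists. Fry still called these lists (adjusted p = 0.000983 and 0.0125), whereas 6 other called lists lost their call with it. The lowest correlation between libraries, 0.952, was 0.978 without a filter, 0.897 at a mean of 4 CPM or more, and 0.953 to 0.974 with a library left out. With RLE or upper-quartile scaling, limma-voom or a fit that was not robust, 1757 to 1991 genes were called. In the simulation, 0 of 50 changes of 1.5-fold were recovered, so changes of that size can be missed. The simulation gave all libraries the same dispersion per gene and changed few genes, unlike these data. The real fit called some smaller changes, such as GADD45A (log2 fold change 0.49) and VEGFA (-0.46), so the simulated recovery is not that of this comparison.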

Other observations

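The Gene Ontology tests, the library-weighted fit, the removal of window medians, the comparison of chromosomes with matched gene sets, the wild-type share, the residual spread after a length or GC trend and the GC comparison with each single library were chosen after the values they bear on had been seen, and the genes named in the next paragraphs were chosen after their values were seen.

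Over 1801 Gene Ontology terms, 4 were enriched among genes higher in the knockout and 17 among genes lower (1-sided Fisher's exact test, adjusted over 3602 tests). The term of lowest p among higher genes was the MHC class II protein complex, where 7 of 11 tested genes rose (adjusted p = 0.000726; 9 without knockout replicate 3). HLA-DRB1 rose from 12.3 ± 0.67 to 31.1 ± 4.07 CPM, HLA-DPA1 from 9.01 ± 0.40 to 22.7 ± 2.94 CPM and HLA-DMB from 6.11 ± 0.27 to 18.2 ± 0.71 CPM (SD, n = 3), whereas CIITA, the transactivator of these genes, lay at 0.60 ± 0.12 and 0.59 ± 0.24 CPM and was not called. HLA genes are close paralogs, so the division of reads between them is uncertain, and exons of HLA-DMB and HLA-DPA1 overlap another annotated gene. Fisher's exact test counts the genes of a term as independent, also where they are close copies or neighbours that change together. Defense response to virus was also enriched among higher genes (15 of 84, adjusted p = 0.0134).

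Among lower genes, cholesterol biosynthetic process (12 of 31, adjusted p = 0.000203), the endoplasmic reticulum unfolded protein response (17 of 80, 0.00181) and the endoplasmic reticulum lumen (24 of 146, 0.00181) were enriched. Terms for which no list was preset included post-translational protein modification (24 of 163, adjusted p = 0.00699), N-linked glycosylation (17 of 90, 0.00511), amino acid transport (9 of 32, 0.0134) and the lysosome (23 of 163, 0.0134). The terms share genes, so they are not separate findings. N-linked glycosylation shared SYVN1 and DERL3 with the unfolded protein response, and DPAGT1 and GANAB, among others, with post-translational protein modification. Amino acid transport included SLC7A11 of the preset NRF2 list. The Gene Ontology tests were not repeated with window medians removed. Of the lower calls placed in windows, 27.1% lay in the 17 windows below the random range, which held 5.5% of the genes. Among the amino acid transporters, SLC7A5 fell from 254 ± 7.84 to 79.7 ± 24.0 CPM, SLC1A5 from 606 ± 6.88 to 348 ± 28.8 CPM and SLC3A2 from 236 ± 4.54 to 158 ± 8.56 CPM. SLC3A2 lies in a window of chromosome 11 with a median log2 fold change of -0.39, so its fall is not separated from that of its neighbours. The regulators of sterol synthesis fell as well: SREBF1 from 92.0 ± 5.50 to 26.4 ± 5.35 CPM and SREBF2 from 386 ± 12.1 to 180 ± 32.6 CPM. Exons of SLC7A5, SLC1A5, SREBF1 and SREBF2 overlap another annotated gene.

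Knockout replicate 3 stood apart from the other knockout libraries. The tables argue against wild-type RNA mixed into the library, since 12 genes at least 8-fold lower in replicates 1 and 2 gave a median wild-type share of -1.02%, the highest being 13.2% for DPP7 and 11% for HSPA5. They also argue against the length or GC content of the longest annotated transcript, each alone, as the whole cause. With the length trend removed, the SD of the ratio to replicates 1 and 2 went from 0.707 to 0.68, still 1.63 times that between replicates 2 and 1. With the GC trend removed, the SD against either library was at least 1.64 times that between replicates 2 and 1. The transcripts expressed may differ from the longest, and the trends were not removed together. A larger effect of length or GC content than these trends capture was therefore not excluded. A part played by length, as partly degraded RNA may give (Spearman rho across genes -0.296), or by GC content stays open, because the rho with GC was -0.0622 against the mean of replicates 1 and 2 but 0.0708 and -0.157 against each, and replicates 2 and 1 themselves differed with GC at 0.434. No biological explanation was tested, because the labels give no day, culture or treatment that sets this library apart; FOS, which was not called, lay at 280 CPM in it against 4.54 and 4.90 CPM in knockout replicates 1 and 2.

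The unfolded protein response, integrated stress response and cholesterol lists were lower together. Knockout replicate 3 alone is argued against, since the highest of the list medians in knockout replicates 1 and 2 was -0.632. Expression level, transcript length and GC content are argued against as well, since the 3 medians lay at percentile 0 of 10000 matched random lists. Loss of NSUN2 remains an untested candidate explanation. It cannot be told apart from a culture state of the wild-type cells, such as a stressed or sterol-poor culture, as the labels name no culture or day. Nor can it be told apart from other differences between the lines, because the labels describe a single knockout line. Every wild-type library lay above every knockout library by at least 0.629 in the list medians, which does not separate these explanations.

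Neighbouring genes changed together over long stretches. The lowest window median, -0.499, lay outside the range of 1000 random gene orders (-0.38 to 0.53), and windows below that range formed runs of 7 on chromosome 9 and 3 on chromosome 11, as a copy number difference between the lines may give. Expression level, length and GC content of these genes are argued against, because the medians of chromosomes 5, 9 and 11 lay at the extreme end of 1000 matched random sets (0% beyond). On the hypothesis of copy number, a change from 4 copies to 3 gives a log2 ratio of -0.42 and from 3 to 4 gives 0.42. The medians were -0.39, -0.34 and 0.36 for chromosomes 9, 11 and 5. That of chromosome 5 mixes windows at 0.05 and -0.02 at its start with windows at 0.27 to 0.59 from WDR70 onward. A change from 4 to 5 gives 0.32, from 2 to 3 gives 0.58, from 3 to 2 gives -0.58 and from 2 to 1 gives -1. The medians therefore do not single out a copy number, and DNA was not analysed here. A copy number difference could have arisen in the knockout line or in the wild-type cells, and it would not account for changes such as that of HSPA5 (log2 fold change -2.87), which exceed the shift of its chromosome.

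Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many called genes, the real split with 1880, and the highest of the other splits called 0 genes in edgeR, with 52 to 727 genes at an unadjusted p under 0.05 against 5901 in the real split; no other tool was run on the splits. The splits are too few for a share under 0.05. Every other split also mixes wild-type and knockout libraries in both groups, so their difference widens the spread within groups and lowers the calls. The counts of the other splits therefore cannot show what a comparison without a true difference would give.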
